A study of Arabidopsis thaliana with 10 samples.

How the data were processed

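Root RNA of the wild type Col, 2 lines of the sdi1sdi2 double knockout (KO) and 2 lines that overexpress SDI1 (OX) was hybridised to ATH1 arrays, per the labels, after 10 days on agar medium with 1500 µM or 15 µM sulfate. RNA was isolated with a column kit and turned into labelled cDNA with a whole-transcript synthesis and terminal labelling kit, per the labels' protocols. Each of the 10 arrays was assigned to its group from its title, 2 arrays in each of 5 groups. All columns of per-sample values were used.

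The deposited values are expression values per probe set on a log10 scale, made by the authors from the array scans. The method of background correction, summarization and normalization is not given in the sources used here, and the zero point of the scale is unknown. The log base was settled from the values: the spiked bacterial controls bioB, bioC, bioD and cre, at nominal 1.5, 5, 25 and 100 pM, spanned 2.13 units on average, against 1.82 expected on a log10 scale, 6.06 on a log2 scale and 4.20 on a natural log scale. The slope against nominal concentration ran from 1.13 to 1.20 over the arrays, so fold changes of bright probe sets may be overstated on this scale. The values ran from -1.15 to 2.94, array medians from 0.126 to 0.137 and 5th percentiles from -0.575 to -0.477, so the arrays share a centre but not a lower tail, and small values may differ between arrays for technical reasons. The values were multiplied by the log2 of 10 to give log2 values, with no pseudocount and no further normalization. An offset before taking logs did not apply.

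Of 22810 probe sets, 554 had no value on any array, 5 of them controls, and 64 were controls. This left 22197 for testing. The platform annotation lists 13513 probe sets with a single gene, 503 with several and none for 8794, and a probe set it does not list is unnamed here. Symbols were updated by Entrez ID with RefSeq gene names of assembly TAIR10.1, which matched 13436 of the 13513, and for list genes the symbol of the fixed list was used for the matching locus. No coordinates are given, since the build behind the array annotation is not stated. A gene was named only from a probe set with a single listed gene.

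The main test was a linear model with a mean for each of the 5 groups over all 10 arrays, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 5 residual degrees of freedom and a prior of 3.81), with Benjamini-Hochberg adjustment over the 22197 probe sets in each of 6 comparisons and a threshold of 0.05. The comparisons were -S against +S in Col and in KO, KO against Col at +S and at -S, OX against Col at +S, and the interaction of KO and sulfate. Background was set per array at the 95th percentile (0.95 quantile) of 22 Bacillus control probe sets, which lay between -0.175 and 0.112 on the deposited scale. Where every array of the lower group lay at or under it, the fold is given as a lower bound: the mean of the brighter group against the mean, over the dim group's arrays, of the higher of the background and the probe set's own value. The bound holds on the scale used here, without correction for the spike-in slope. No fold is given where both groups lay under the background.

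Before the data were examined, 23 gene lists with 352 genes, the tests and the alternatives were fixed. The annotation named probe sets for 48 of the list genes, 5 lists had no measured member, and the 9 lists with at least 3 were tested with camera (preset correlation, 1 probe set per gene with the highest mean, 12918 genes), beside camera with an estimated correlation and fry, adjusted over 9 lists. A list's test here rests on 3 to 6 members and says little about the members that were not measured. The named genes were, also by a rule fixed before the data were examined, the 10 largest rises and 10 largest falls in each comparison among called probe sets with a single gene whose arrays did not overlap between groups (without this condition for the interaction), all where fewer passed, SDI1 and SDI2 in every comparison, up to 4 members of each described list by moderated t statistic, and any member of the lists of sulfur deficiency markers, aliphatic glucosinolate synthesis and glucosinolate regulators.

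Correlations of fold changes between comparisons that share control arrays were set beside 100 simulated data sets without any change. KO arrays of the same line at +S and -S come from the same plant line and are paired by it. Their deviations from the group means correlated at 0.07, and the Col arrays, which share only a number, at -0.14. Alternatives tried were quantile normalization, median centring, omission of the dimmest probe sets by mean level, an intensity trend with robust variances, only the arrays of the groups compared, array weights, blocks for mutant line and label number, 1 probe set per gene, the mean over a gene's probe sets in the list tests, and leaving out each of the 10 arrays in turn. Added after the data were seen were a filter on background, tests of gene families, and separate Col +S arrays as controls where comparisons share them. The fit was tested on simulated arrays with 200 changed probe sets: for Col at low sulfate it recovered 95% of changes of 1 log2 unit and 100% of changes of 2, with 5.3% of calls false. For the interaction it recovered 60% and 98%, with 5.4% of calls false. The share of false calls was highest for KO against Col at +S, 7.7%, and for OX against Col, 6.7%. It lay above the threshold in every comparison except KO at low sulfate, 2.6%. Figures were drawn with matplotlib 3.10.9.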

Results

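Root RNA of Arabidopsis thaliana was profiled on 10 ATH1 arrays, a short-oligonucleotide array with 22810 probe sets, after 10 days of growth. The plants were the wild type Columbia (Col), the sdi1sdi2 double knockout (KO, lines 1 and 4) and plants that overexpress SDI1 (OX, lines 6 and 12). SDI1 and SDI2 are genes whose transcripts accumulate when sulfur is short. Col and KO were grown at 1500 µM sulfate (+S) or at 15 µM sulfate (-S), and OX at +S only, which gave 5 groups of 2 arrays. Values below are on a log2 scale, group values are mean ± SD with n = 2, changes are log2 fold changes ± SE of the fit, and adjusted p-values come from limma with Benjamini-Hochberg adjustment over 22197 probe sets. Arrays within a group correlated at 0.9904 to 0.9959, and the lowest correlation between any arrays was 0.972. The p-values measure a spread pooled over the 5 groups. In KO and OX the 2 arrays of a group are 2 lines. The pooled spread therefore holds differences between lines, also where only Col groups are compared. The labels do not say whether the 2 Col arrays of a group came from separate cultures, so their spread may be partly technical. The number of arrays limits the precision.

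SDI2 (AT1G04770) was the targeted gene that the probe annotation listed. Its level was 1.70 ± 0.18 in Col +S and 5.56 ± 0.13 in Col -S, against -0.76 ± 0.58 in KO +S, -0.61 ± 1.29 in KO -S and 1.69 ± 0.24 in OX. The KO arrays of line 1 read -0.35 at +S and 0.31 at -S, and those of line 4 read -1.16 and -1.52, so the lines differed more from each other than the Col arrays did. Both line 4 arrays lay under their background levels (-0.52 at +S and -0.05 at -S). Both line 1 arrays lay above theirs (-0.51 and -0.58). The size of the line difference, and of each SDI2 change that involves KO, is therefore approximate. At -S the difference of KO from Col was -6.16 ± 0.50 (limma adjusted p = 0.00021), and at +S it was -2.45 ± 0.50 (limma adjusted p = 0.26). Where the insertions lie relative to this probe set is not given in the sources used here, and a probe set outside the disrupted part would check nothing. No probe set was listed for SDI1, so its level was not analysed here by name. Among the probe sets without a listed gene, 248676_at had the largest rise in OX and was chosen after its values were seen. It stood at 8.24 ± 0.41 in OX and 8.99 ± 0.19 in Col -S, and at -1.02 ± 0.08 in Col +S, -1.19 ± 0.27 in KO +S and -1.56 ± 0.22 in KO -S. It was the only 1 of the tested probe sets that was higher by over 4 in both Col -S and OX and lower by over 4 in KO -S than in Col -S. Which gene 248676_at measures is not given in the annotation used here, and the overexpression itself was therefore not checked by gene name.

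**Figure D1:**
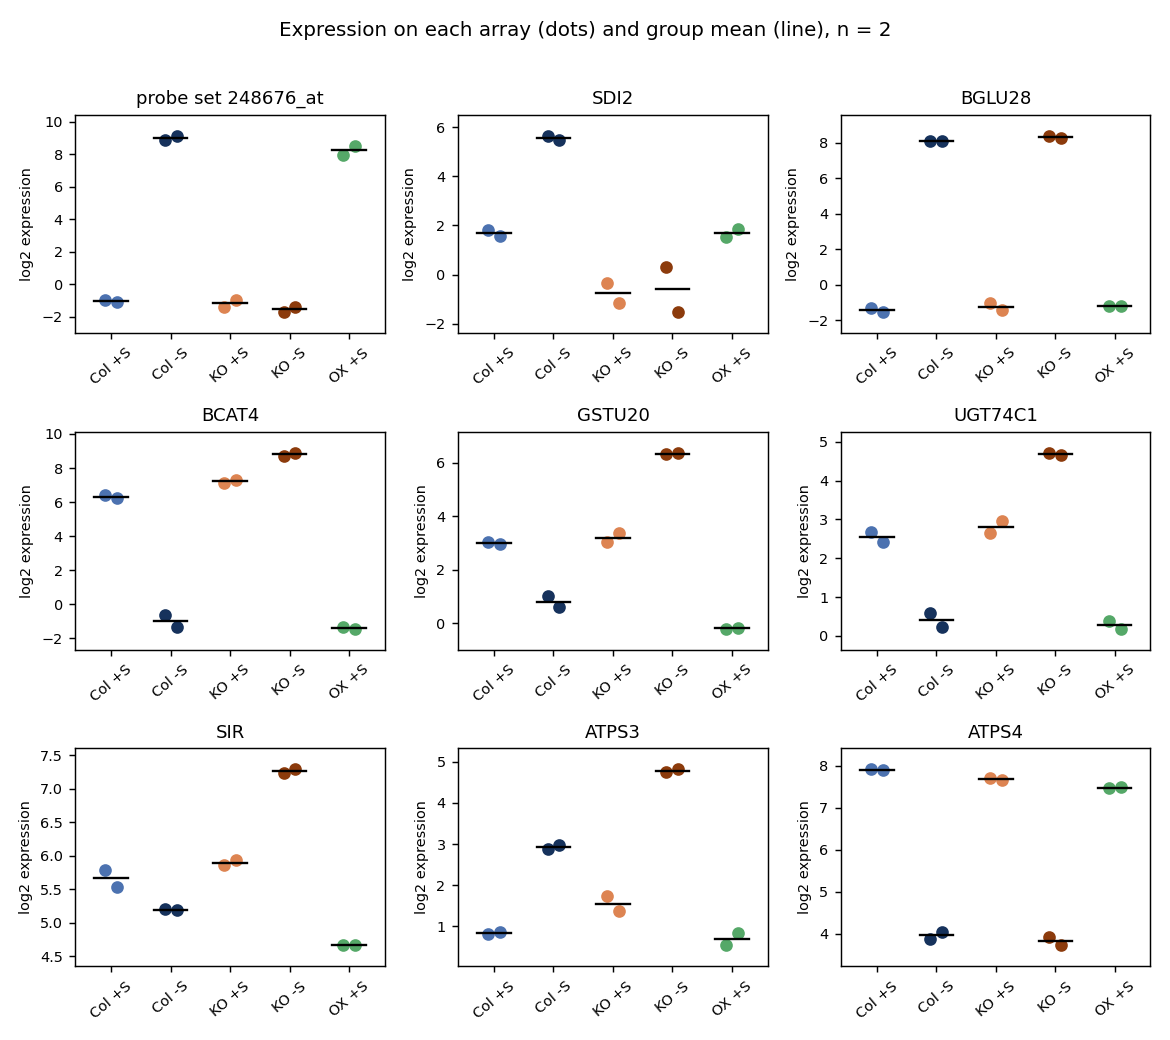
Expression on each array (dots, log2 scale) with the group mean (line, n = 2) for 9 probe sets in the 5 groups. BCAT4 lies at 6.31 in Col +S, at -0.99 in Col -S, at 8.80 in KO -S and at -1.38 in OX, while BGLU28 lies at 8.10 in Col -S and 8.33 in KO -S and below -1 in every +S group.

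The first comparison asked how wild-type roots respond to low sulfate. BGLU28, a beta-glucosidase that hydrolyses glucosinolates, rose from -1.43 ± 0.13 to 8.10 ± 0.03. Because Col +S lay under the background level, this was a rise of at least 365-fold (limma adjusted p = 4.7e-09). Such bounds hold on the scale used here, without correction for the spike-in slope. BCAT4, the aminotransferase that starts methionine chain elongation for aliphatic glucosinolates, fell from 6.31 ± 0.13 to -0.99 ± 0.51, at least 76.9-fold (limma adjusted p = 1.2e-07). Of the ATP sulfurylases, which activate sulfate for assimilation, ATPS4 fell by 3.94 ± 0.11 and ATPS3 rose by 2.1 ± 0.14. SDI2 rose by 3.86 ± 0.50 (limma adjusted p = 0.0018).

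Low sulfate changed 2095 probe sets in Col, 985 higher and 1110 lower, of which 186 rose and 262 fell at least 2-fold. The other large rises among named genes were AT1G12030 (at least 25.9-fold), the sugar transporter family member AT3G05400 (at least 33.1-fold), AT4G31330 (5.65 ± 0.15), the isoflavone reductase-like AT1G75280 (4.09 ± 0.10) and AT1G75290 (at least 7.47-fold), AT5G04120 (3.90 ± 0.43), the amino acid transporter family member AT3G56200 (2.9 ± 0.14) and AT5G37980 (at least 4.74-fold). The other large falls were AT4G39675 (-2.9 ± 0.13), AT2G25450, a hydroxylase gene of aliphatic glucosinolates (-2.69 ± 0.11), AT2G28780 (-2.66 ± 0.12), AT3G15450 (-2.61 ± 0.22), ATL8 (-2.46 ± 0.24), AT1G21440 (-2.45 ± 0.11), AT4G07820 (-2.45 ± 0.19) and AT1G23390 (-2.38 ± 0.14). Limma adjusted p-values of these genes were all at or below 0.00083.

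In the fixed list of aliphatic glucosinolate synthesis, 4 of 24 genes were measured and 3 of these fell: BCAT4, the glutathione transferase GSTU20 (-2.2 ± 0.15) and the glucosyltransferase UGT74C1 (AT2G31790, -2.15 ± 0.16), while AOP3 lay under the background level in both groups. Adjusted over the list alone, 3 also fell. The list's mean was -2.98 (camera adjusted p = 2.6e-07 over 9 lists, and adjusted p = 0.1 with an estimated correlation). Of the sulfate assimilation list, ATPS3 rose and ATPS4 and the sulfite reductase SIR (-0.47 ± 0.10) fell, 3 of 22 genes being measured (camera adjusted p = 0.17, 1 rose and 2 fell adjusted over the list alone). In the list of glucosinolate breakdown and transport, 2 of 4 measured members rose, BGLU28 and the importer GTR1 (by 2.34 ± 0.19), GTR2 fell by 0.91 ± 0.15, and the beta-glucosidase PYK10 stood at -0.02 ± 0.15. Its camera adjusted p was 0.04, and adjusted p = 0.25 with an estimated correlation, with 2 rising and 1 falling adjusted over the list alone.

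The 3 measured photosynthesis genes, RCA, LHCB4.1 and PSAE1, all fell (-0.93 ± 0.17, -0.69 ± 0.11 and -0.77 ± 0.18, camera adjusted p = 0.00097, and adjusted p = 0.1 with an estimated correlation), and all 3 fell adjusted over the list alone. Of the iron deficiency list, F6H1 fell by 0.68 ± 0.11 and PYE stood at 0.09 ± 0.11, while BHLH101 passed the test with both groups under the background level (camera adjusted p = 0.043, adjusted p = 0.19 with an estimated correlation, 2 falling adjusted over the list alone). The lists of flavonoid synthesis (5 members, none called, camera adjusted p = 0.52), auxin response (6 members, of which GH3.1 was called with both groups under the background level, camera adjusted p = 0.71), the SDI family (SDI2 rose, MS5L2 stood at 0.21 ± 0.10 and MS5L1 lay under the background level, camera adjusted p = 0.17) and reference genes (4 members, none called, camera adjusted p = 0.87) did not stand apart. Both measured root hair expansins rose, EXPA7 by 0.76 ± 0.14 and EXPA18 by 0.77 ± 0.15. UGT74B1, the glucosyltransferase of the indolic glucosinolate list, fell by 0.73 ± 0.13. Of the list of glucosinolate regulators only 2 of 12 genes were measured. These, the transcription factors MYC3 and MYC4, stood at -0.29 ± 0.19 and -0.21 ± 0.24. GSTU25 and the glutathione reductase GR1 rose by 1.08 ± 0.20 and 0.38 ± 0.09. Of lists with 1 or 2 measured members, IGPS of tryptophan synthesis (-0.15 ± 0.10), SGN3 of the endodermis (0.29 ± 0.09), and AUR1 and AUR2 of the cell cycle (0.19 ± 0.11 and 0.06 ± 0.12) were not called, and the defensins PDF1.2A and PDF1.2B lay under the background level. The lists of sulfate transporters, jasmonate, phosphate starvation, nitrate, and xylem and phloem had no measured member.

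The count of 2095 in Col was 897 without Col +S 1, 990 without Col +S 2 and 1143 without Col -S 2. Of the 10 fits that left out 1 array, the call of GR1 was lost in 6, that of SIR in 5, those of PSAE1 and EXPA18 in 4, that of GSTU25 in 3, those of RCA, EXPA7 and UGT74B1 in 2, and those of LHCB4.1 and F6H1 in 1 (without Col +S 2) and BHLH101 in 1 (without Col +S 1). The call of the iron list was lost in 5 (without Col -S 1, adjusted p = 0.081, Col +S 1, 0.055, Col +S 2, 0.05, not called before rounding, or either OX array, 0.063). That of the breakdown and transport list was lost in 4 (without Col -S 1, adjusted p = 0.15, Col +S 1, 0.073, or either OX array, 0.063). With a block for mutant line the calls of PSAE1, GR1 and the iron list (adjusted p = 0.055) were lost too.

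**Figure D2:**
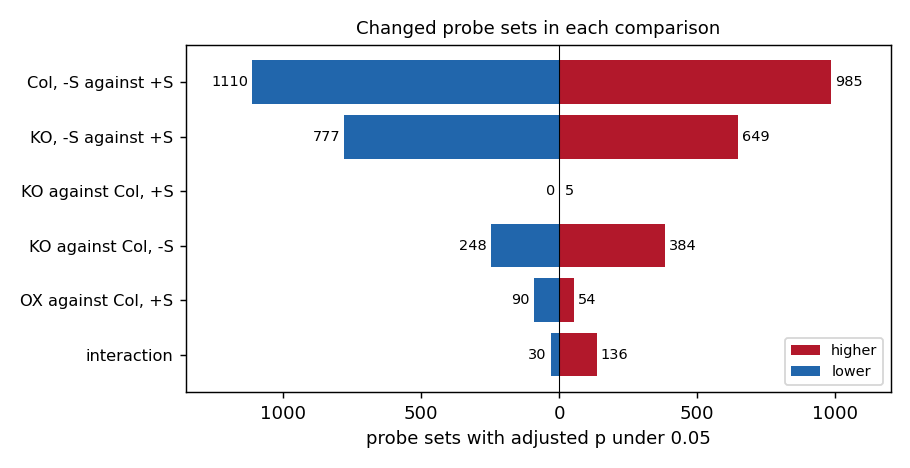
Number of probe sets with a limma adjusted p under 0.05 in each of the 6 comparisons, higher to the right and lower to the left. Low sulfate changed 2095 in Col and 1426 in KO, and KO differed from Col in 5 at +S and in 632 at -S.

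The second comparison asked for the same response in the double knockout. BGLU28 rose at least 457-fold, from -1.23 ± 0.28 to 8.33 ± 0.07, and ATPS4 fell by 3.87 ± 0.11, while genes of aliphatic glucosinolate synthesis rose: BCAT4 by 1.59 ± 0.21 (limma adjusted p = 0.0023), GSTU20 by 3.15 ± 0.15 (limma adjusted p = 5.5e-06) and UGT74C1 by 1.88 ± 0.16 (limma adjusted p = 0.00017). SIR rose by 1.37 ± 0.10 and ATPS3 by 3.23 ± 0.14. SDI2 differed by 0.15 ± 0.50 between the sulfate levels in KO (limma adjusted p = 0.93).

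Low sulfate changed 1426 probe sets in KO, 649 higher and 777 lower, with 220 and 192 of these at least 2-fold. Both genotypes shared 361 that rose and 456 that fell, against 28.8 and 38.9 for independent lists of these lengths, and 43 moved in opposite directions. Of the 43, 42 fell in Col and rose in KO, against 32.5 for independent lists, and 1 went the other way, against 34.5. The other named rises were AT1G12030 (at least 75.8-fold), AT3G05400 (at least 50.3-fold), AT4G31330 (4.47 ± 0.15), AT1G75290 (at least 12.7-fold), AT1G75280 (4.17 ± 0.10), the annotated pseudogene AT4G05550 (at least 9.37-fold) and AT1G66760 (3.09 ± 0.14). The other named falls were AT4G07820 (-3.43 ± 0.19), AT3G12900, a scopoletin hydroxylase gene (at least 5.5-fold), AT4G39675 (-2.65 ± 0.13), ATL8 (-2.55 ± 0.24), AT5G56100 (-2.39 ± 0.16), AT2G28780 (-2.38 ± 0.12), the glycerate kinase AT1G80380 (-2.36 ± 0.24), the calmodulin-like CML38 (-2.31 ± 0.57, limma adjusted p = 0.048) and AT5G60760 (-2.27 ± 0.10).

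Of the aliphatic glucosinolate list, 3 of 4 measured members rose, with AOP3 under the background level, and a list mean of 1.70 (camera adjusted p = 1.1e-06, and adjusted p = 0.12 with an estimated correlation) and 3 rising adjusted over the list alone. Of sulfate assimilation, 2 of 3 rose and ATPS4 fell, which was also the count adjusted over the list alone (camera adjusted p = 0.14). GTR1 rose by 1.57 ± 0.19 and GTR2 stood at -0.22 ± 0.15, so that 2 of 4 members of the breakdown and transport list rose, as they did adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.17 with an estimated correlation). LHCB4.1 fell by 0.67 ± 0.11, and RCA and PSAE1 stood at -0.58 ± 0.17 and -0.55 ± 0.18 (camera adjusted p = 0.004, adjusted p = 0.12 with an estimated correlation), with 3 falling adjusted over the list alone. UGT74B1 rose by 0.96 ± 0.13, GSTU25 by 1.56 ± 0.20 and GR1 by 0.52 ± 0.09. The iron list had 1 of 3 members called, BHLH101, with both groups under the background level (camera adjusted p = 0.027, adjusted p = 0.16 with an estimated correlation). No member of the SDI, flavonoid, auxin or reference lists was called (camera adjusted p = 0.8, 0.33, 0.33 and 0.94). The count of 1426 was 564 without KO +S 1, 842 without KO +S 4, 677 without KO -S 4 and 910 without KO -S 1. Of the 10 fits that left out 1 array, the call of CML38 was lost in 7, that of BHLH101 in 4, and those of LHCB4.1 and GR1 in 3. The call of the iron list was lost without KO -S 1 (adjusted p = 0.055) or KO +S 1 (0.084), and with only the arrays compared that of the breakdown and transport list was (0.11).

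The third comparison set the double knockout against Col at full sulfate. AT4G40070, a RING finger gene, was higher in KO by 2.14 ± 0.13 (limma adjusted p = 0.00048) and AT1G61740, a sulfite exporter family member, by 1.79 ± 0.10 (limma adjusted p = 0.00036). The other 3 called probe sets, 250475_at, 265897_at and 267035_at, have no listed gene and were higher by 1.62 ± 0.17, 2.03 ± 0.15 and 2.26 ± 0.12 (chosen for naming after their values were seen). BCAT4 stood at 0.90 ± 0.21 (limma adjusted p = 0.36), GSTU20 at 0.19 ± 0.15 and UGT74C1 at 0.25 ± 0.16.

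In all, limma called 5 probe sets higher and 0 lower, with 1235 at an unadjusted p under 0.05, where 1110 would be expected by chance. All 5 were also higher in KO at -S. No member of any fixed list was called. By camera the aliphatic list (mean 0.30, adjusted p = 0.015, and adjusted p = 0.36 with an estimated correlation) and the breakdown and transport list (mean 0.31, adjusted p = 0.0051, and adjusted p = 0.21 with an estimated correlation) stood higher, with 1 member each called adjusted over the list alone, BCAT4 and GTR1 having the largest values. Adjusted over the list alone, 1 member was also higher in sulfate assimilation and in flavonoid synthesis, and 1 lower in the SDI family, where SDI2 had the largest difference. The photosynthesis list stood lower (mean -0.36, camera adjusted p = 0.0051, and adjusted p = 0.2 with an estimated correlation; 1 member called adjusted over the list alone). The sulfate assimilation list had a mean of 0.24 (camera adjusted p = 0.053). The aliphatic list's call was lost without Col +S 2 (adjusted p = 0.29) or KO +S 4 (0.18), that of photosynthesis without Col +S 2 (0.29) and that of breakdown and transport without KO +S 1 (0.072). The count of 5 was 59 without KO +S 4, 8 after quantile normalization, 31 with an intensity trend and robust variances, 32 without the dimmest probe sets and 69 with array weights, the last with 48 higher and 21 lower.

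The fourth comparison set the double knockout against Col at low sulfate. BCAT4 was higher in KO at least 432-fold (8.80 ± 0.14 against -0.99 ± 0.51, limma adjusted p = 5.2e-08), GSTU20 by 5.54 ± 0.15 (limma adjusted p = 1.8e-07), UGT74C1 by 4.29 ± 0.16 (limma adjusted p = 8.7e-07) and the hydroxylase gene AT2G25450 by 4.29 ± 0.11 (limma adjusted p = 1.2e-07). SIR was higher by 2.06 ± 0.10, ATPS3 by 1.85 ± 0.14 and UGT74B1 by 2.07 ± 0.13. BGLU28 did not differ detectably, at 0.23 ± 0.14 (limma adjusted p = 0.40).

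KO differed from Col at -S in 632 probe sets, 384 higher and 248 lower, of which 155 and 35 were at least 2-fold. The other named genes that were higher in KO were AT1G21440 (4.36 ± 0.11), AT4G40070 (at least 4.28-fold), AT2G43550 (2.89 ± 0.16), AT3G23570 (2.85 ± 0.11), AT4G05550 (2.46 ± 0.22) and AT1G61740 (2.43 ± 0.10). After SDI2, the named genes that were lower in KO were AT5G61290 (-1.90 ± 0.11), AT4G14060 (-1.42 ± 0.15), the sugar transporter SWEET14 (at least 2.19-fold), the sulfurtransferase STR18 (-1.37 ± 0.11), AT5G39670 (-1.33 ± 0.20), the expansins EXPB3 (-1.27 ± 0.15) and EXLB1 (-1.24 ± 0.12) and AT5G37450 (-1.19 ± 0.14). AT3G19690 also passed, with both groups under the background level.

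Of the aliphatic glucosinolate list 3 of 4 measured members were higher and AOP3 lay under the background level (list mean 4.98, camera adjusted p = 6.5e-13, and adjusted p = 0.042 with an estimated correlation), also 3 adjusted over the list alone. In sulfate assimilation 2 of 3 were higher and ATPS4 stood at -0.14 ± 0.11 (mean 1.26, camera adjusted p = 0.00022, and adjusted p = 0.042 with an estimated correlation), again 2 adjusted over the list alone. GTR2 was higher by 0.90 ± 0.15 and IGPS, of tryptophan synthesis, by 0.60 ± 0.10, with GTR1 at 0.05 ± 0.19 (breakdown and transport list, camera adjusted p = 0.22). The auxin list had GH3.1 called with both groups under the background level, a call lost in 7 of the 10 fits that left out 1 array and with a block for mutant line (camera adjusted p = 0.067). EXPA7 stood at -0.64 ± 0.14 (limma adjusted p = 0.051) and EXPA18 at -0.44 ± 0.15. The photosynthesis genes RCA, LHCB4.1 and PSAE1 stood at -0.16 ± 0.17, -0.22 ± 0.11 and -0.12 ± 0.18 (camera adjusted p = 0.41). MYC3 and MYC4 stood at 0.06 ± 0.19 and -0.16 ± 0.24. The count of 632 was 252 without Col -S 2 (186 higher and 66 lower), 274 without KO -S 1 (202 and 72) and 304 without KO -S 4 (228 and 76). The lower count alone was 370 without Col -S 1, 153 without either KO +S array and 38 with only the arrays compared. The calls of AT3G19690 and IGPS were each lost without Col -S 2, KO -S 1 or KO -S 4, that of GTR2 without Col -S 2 or KO -S 1, and that of AT5G39670 without KO -S 4.

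The interaction test asked whether the response to low sulfate differed between KO and Col. Among called probe sets with a single listed gene, the largest positive interactions, meaning a response that was higher in KO, were those of BCAT4 (8.89 ± 0.30, limma adjusted p = 2.5e-06, with Col -S under the background level so that the size is approximate), GSTU20 (5.35 ± 0.21, limma adjusted p = 6.2e-06), AT1G21440 (4.16 ± 0.16, limma adjusted p = 4.8e-06), UGT74C1 (4.03 ± 0.23, limma adjusted p = 4.1e-05) and AT2G25450 (3.66 ± 0.15, limma adjusted p = 7e-06). Among the same probe sets, the largest negative interactions were those of AT5G39670 (-1.81 ± 0.28), AT1G49700 (-1.74 ± 0.21, approximate since Col +S and KO -S lay under the background level) and AT5G61290 (-1.70 ± 0.16). SDI2, which was not called, had an interaction of -3.71 ± 0.70 (limma adjusted p = 0.064), and 248676_at, without a listed gene, had a negative interaction that was called (limma adjusted p = 1.1e-06).

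The interaction was called in 166 probe sets, 136 positive and 30 negative. Of the 166, 82 fell in Col, and of these 82 in KO 42 rose, 5 fell and the rest were not called. SIR (1.83 ± 0.15, limma adjusted p = 0.00047) and UGT74B1 (1.69 ± 0.19, limma adjusted p = 0.0038) were called too. ATPS3 stood at 1.13 ± 0.20 (limma adjusted p = 0.05, counted as called before rounding). Its call was not among those followed below when 1 array was left out. BGLU28, under the background level at +S, and ATPS4 stood at 0.03 ± 0.19 and 0.07 ± 0.15, both with adjusted p-values above 0.9 by limma. In the aliphatic list 3 of 4 measured members were called positive (mean 4.68, camera adjusted p = 2.2e-15, and adjusted p = 0.027 with an estimated correlation), 3 adjusted over the list alone. In sulfate assimilation 2 of 3 were positive (mean 1.01, camera adjusted p = 2.9e-05, and adjusted p = 0.027 with an estimated correlation), 2 adjusted over the list alone. The photosynthesis list had a mean of 0.19 (camera adjusted p = 0.34). The count of 166 was 84 without KO +S 1, 88 without Col +S 1, 106 without KO -S 1, 108 without KO -S 4 and 110 without Col -S 2, and without KO +S 4 it was 205, of which 95 were positive and 110 negative. Without Col +S 2 the positive ones were 85. Of the 10 fits that left out 1 array, the calls of AT1G58420 (-1.55 ± 0.25) and AT2G18210 (-1.4 ± 0.23) were lost in 9, that of AT4G14060 (-1.42 ± 0.22) in 6, that of AT5G39670 in 5, that of AT5G63130 (-1.23 ± 0.18) in 4 and that of AT5G44820 (-1.25 ± 0.16) in 2. The sizes for AT1G58420 and AT5G44820 are approximate since Col +S and KO -S lay under the background level.

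The last comparison set SDI1 overexpression against Col at full sulfate. BCAT4 fell at least 87.6-fold, from 6.31 ± 0.13 to -1.38 ± 0.06 (limma adjusted p = 4.3e-07), GSTU20 fell by 3.2 ± 0.15 (limma adjusted p = 1.8e-05), UGT74C1 by 2.27 ± 0.16 (limma adjusted p = 0.00028) and AT2G25450 by 2.43 ± 0.11 (limma adjusted p = 1.1e-05). SIR fell by 1.00 ± 0.10 (limma adjusted p = 0.0036). AT5G04120 rose by 3.07 ± 0.43 (limma adjusted p = 0.017), and the cold-regulated COR27 rose at least 1.87-fold (limma adjusted p = 0.00057). BGLU28 stood under the background level in both groups, and SDI2 differed by -0.01 ± 0.50.

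OX changed 144 probe sets, 54 higher and 90 lower, of which 25 and 52 were at least 2-fold. The other named rises were AT4G33980 (1.97 ± 0.21), AT5G47980 (1.85 ± 0.18), AT5G11420 (1.45 ± 0.15), AT5G66590 (1.22 ± 0.14), the xyloglucan endotransglucosylase XTH19 (1.2 ± 0.21, limma adjusted p = 0.046), AT1G56300 (1.08 ± 0.13) and the pyruvate decarboxylase PDC2 (1.06 ± 0.12). The response regulator RR16 passed with both groups under the background level. The other named falls were AT1G21440 (-3.5 ± 0.11), AT3G14280 (-1.91 ± 0.12), AT2G01610 (-1.63 ± 0.12), EXPB3 (-1.11 ± 0.15), AT3G45700 (-1.1 ± 0.12) and AT2G36690 (at least 1.34-fold).

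Of the aliphatic glucosinolate list 3 of 4 measured members fell and AOP3 lay under the background level in both groups (list mean -3.25, camera adjusted p = 1.4e-13, and adjusted p = 0.029 with an estimated correlation), 3 adjusted over the list alone. In sulfate assimilation SIR fell, and ATPS4 and ATPS3 stood at -0.43 ± 0.11 and -0.16 ± 0.14 (camera adjusted p = 2e-05, and adjusted p = 0.029 with an estimated correlation), with 2 falling adjusted over the list alone. No member of the breakdown and transport list was called, GTR1 standing at 0.75 ± 0.19 and GTR2 at -0.45 ± 0.15 (camera adjusted p = 0.98, 1 rising and 1 falling adjusted over the list alone). RCA stood at -0.90 ± 0.17 (limma adjusted p = 0.065), and the photosynthesis list lay lower (camera adjusted p = 0.0061, adjusted p = 0.079 with an estimated correlation, 1 member falling adjusted over the list alone). UGT74B1 stood at -0.37 ± 0.13, MYC3 at 0.09 ± 0.19 and MYC4 at -0.11 ± 0.24. The call of the photosynthesis list was lost without Col +S 2 (adjusted p = 0.11) or OX +S 12 (0.25). The count of 144 was 36 without Col +S 1, 58 without Col +S 2, 50 without OX +S 6, 79 without OX +S 12 and 94 without either KO +S array. Of the 10 fits that left out 1 array, the call of XTH19 was lost in 9 (and with a block for mutant line), those of AT5G04120 (without Col +S 1, Col +S 2 or OX +S 12), AT5G66590 and EXPB3 in 3, those of AT1G56300, PDC2 and AT3G45700 in 2, and that of AT5G11420 in 1 (without Col +S 1).

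BCAT4, GSTU20, UGT74C1, SIR, AT2G25450 and AT1G21440 were among 44 probe sets that were lower in OX at +S and higher in KO at -S, 2 comparisons that share no array. Independent lists of these lengths would share 1.56. There were 63 probe sets called in both, 48 of them in opposite directions. The other 15 went in the same direction, 7 higher in both against 0.934 for independent lists and 8 lower, EXPB3 among them, against 1.01. Across all probe sets, which are not independent replicates, the log2 fold changes correlated at -0.39 (Spearman -0.17), with a covariance of -0.0344 and a simulated correlation of 0 for unchanged groups, and at -0.14 over the probe sets called in neither. In all, 3 relations of this kind were computed, all across probe sets.

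The changes in OX and those in Col at low sulfate share the Col +S arrays. Their correlation was 0.43, where unchanged groups simulated against shared controls gave 0.50, and the covariance was 0.0444 against a simulated 0.0127, a difference of 0.0317. BCAT4, GSTU20, UGT74C1 and SIR were among 58 probe sets that fell in both, against 4.5 for independent lists. AT5G04120 and XTH19 were among 25 that rose in both, against 2.4. Their calls in OX were lost in 3 and 9 of the 10 fits that left out 1 array. With Col +S 1 as the only control of OX and Col +S 2 of Col at -S, a test chosen after seeing the data, the correlation was 0.3, and 26 fell and 4 rose in both, against 0.774 and 0.424. The other way round it was 0.25, and 25 fell and 3 rose in both, against 0.59 and 0.219. BCAT4, GSTU20 and UGT74C1 were among those that fell in both either way. For OX and KO at +S, which share the same arrays, the correlation was 0.28 (0.48 without Col +S 2 and 0.17 without OX +S 12) against a simulated 0.50, and the covariance was 0.0135 against 0.0127. With the Col +S arrays split in the same manner it was 0.19 and -0.1, so that its direction was not settled. Of these comparisons, 3 probe sets were called in both, all lower in OX and higher in KO, AT4G40070 among them.

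**Figure D3:**
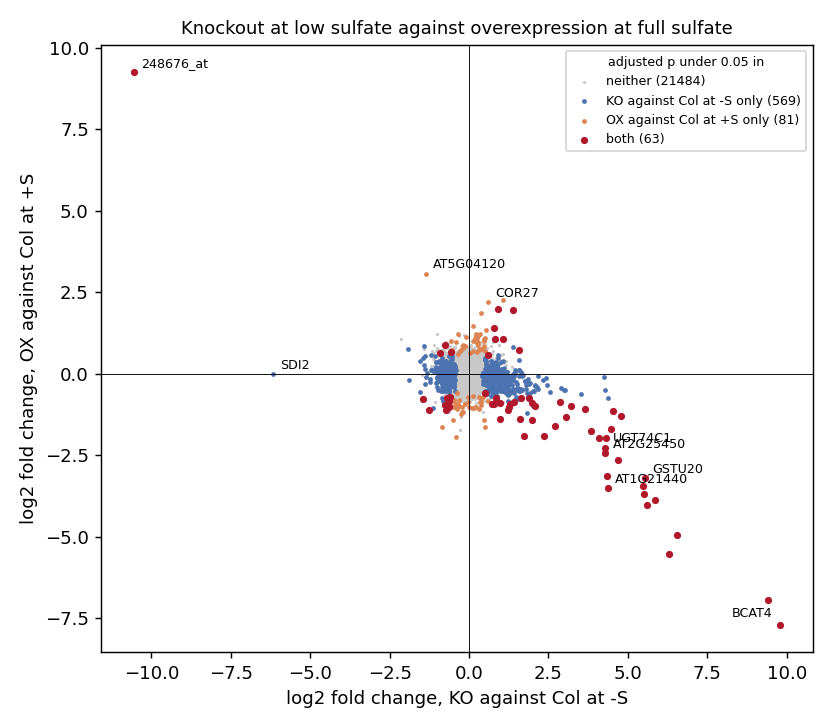
Log2 fold change of every tested probe set in KO against Col at -S (x axis) and in OX against Col at +S (y axis), coloured by the comparison in which the limma adjusted p was under 0.05. BCAT4 lies at the lower right and probe set 248676_at at the upper left, both measured on each axis against a group under the background level so that their positions are approximate, and 48 of the 63 probe sets called in both moved in opposite directions.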

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

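In this part the tests of shared calls, of the interaction as an explanation and of clock genes were chosen only after the result was seen. The response to low sulfate differed between KO and Col, by the interaction test itself, in 166 probe sets. The mean interaction of the aliphatic glucosinolate synthesis list was 4.68 and that of the sulfate assimilation list 1.01. Single genes with a higher response in KO were BCAT4 (8.89), GSTU20 (5.35), AT1G21440 (4.16), UGT74C1 (4.03), AT2G25450 (3.66), AT3G23570 (2.83), AT2G43550 (2.53), AT4G05550 (2.35), AT4G01870 (2.07) and AT1G60750 (2.02). Those with a lower response in KO were AT5G39670 (-1.81), AT1G49700 (-1.74), AT5G61290 (-1.70), AT1G58420 (-1.55), AT4G14060 (-1.42), AT2G18210 (-1.40), STR18 (-1.32), SWEET14 (-1.27), AT5G44820 (-1.25) and AT5G63130 (-1.23), in log2 units. BCAT4 in Col -S, and 1 or more groups of AT4G05550, AT1G60750, AT1G49700, AT1G58420, SWEET14 and AT5G44820, lay under the background level, so these sizes are approximate.

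BCAT4, GSTU20, UGT74C1 and SIR went down in OX at +S and up in KO at -S, and fold changes of these comparisons correlated at -0.39. Unequal lower tails of the arrays are argued against as the whole cause, because the correlation was -0.38 after quantile normalization, with a spread of 0.07 between single-array versions. Whether a few strongly changed probe sets carry the relation stays open, since over the 21484 probe sets called in neither comparison it was -0.14 with a spread of 0.14. The overlap of 44 probe sets lower in OX and higher in KO, against 1.56 for independent lists, restates the pattern, so whether genes lowered by SDI1 rise when SDI1 and SDI2 are lost at low sulfate was not tested independently and stays open.

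KO and Col differed in 632 probe sets at -S and in 5 at +S. The array Col -S 2, which has the highest background level, does not account for this by itself, since 252 probe sets still differed at -S without it. After quantile normalization 669 differed at -S and 8 at +S, which argues against unequal lower tails as the cause. The interaction test, which compares the responses directly, called 166 probe sets, in line with a dependence of the knockout effect on sulfate supply as a hypothesis. The size of the contrast stays open, because without KO +S 4 the count at +S was 59.

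COR27, AT4G33980 and PDC2 rose in OX, and in KO none of them was called at +S (limma adjusted p = 0.088, 0.088 and 0.087, with AT4G33980 at 1.49 ± 0.21 and PDC2 at 0.95 ± 0.12) while at -S AT4G33980 (Col under the background level, limma adjusted p = 0.0096) and PDC2 (1.06 ± 0.12, limma adjusted p = 0.002) were higher and COR27 lay under the background level in both groups. The Col +S arrays that the comparisons at +S share were checked as a cause at -S, where the Col arrays are others. There, 40 probe sets that rose in OX and were higher in KO at +S with an unadjusted p under 0.05 had a median difference of 0.32 ± 0.06. Of the 40, 32 lay above 0 and 8 below 0, with 6 called higher and 1, SWEET13, called lower (-0.92). The SE comes from resampling probe sets read on the same arrays, so it holds no spread between arrays. The shared arrays are thus argued against only for the KO difference of the 6 called higher. The rise in OX was measured only against the Col +S arrays, so for it, and for the other probe sets, this stays open. All 54 probe sets that rose in OX had a median of 0.24 ± 0.05 in KO at -S, with an SE of the same kind. Of these, 7 were called higher and 4 lower. Opposite effects of gain and loss of SDI1 do not account for the 7, and for the set as a whole this stays open. A different time of day or temperature at harvest could raise such genes in both kinds of mutant and cannot be told apart from the genotypes. In OX, GI differed by 0.52 ± 0.10 (limma adjusted p = 0.06) and AT5G52660 by 0.16 ± 0.10 (limma adjusted p = 0.75). In KO, GI stood at 0.51 ± 0.10 at +S (limma adjusted p = 0.21) and 0.34 ± 0.10 at -S (limma adjusted p = 0.11). AT5G52660 stood at 0.06 ± 0.10 and 0.04 ± 0.10 there. None of these was called, and no label gives a harvest time.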

How the results depend on the processing

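Single calls were followed only for the named genes and list members, and other called probe sets were not followed one by one. None of the followed genes or lists that were called changed direction under any alternative run. The correlation of OX with KO at +S did, as given below. Of 137 gene calls in the 6 comparisons, 136 held after quantile normalization and 120 in fits with only the arrays compared, and 103 held in all 10 fits that left out 1 array, where the lone array of a group is assumed to vary like the others. The 54 list tests held 18 calls. Of these 18, 12 were lost by camera with an estimated correlation, the aliphatic list in Col (-2.98, adjusted p = 0.1) among them. With fry 3 were lost and 7 gained. Of 18 list calls, 11 held in all 10 fits that left out 1 array, 3 were lost with only the arrays compared, 1 with a block for mutant line (iron in Col) and 2 with the Col number as a second block. The log offset listed for linear values was not run, since the values are logs. Counts below name Col -S against +S, KO -S against +S, KO against Col at +S and at -S, OX against Col and the interaction by these words, and the cause of a change was not tested unless stated.

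KO against Col at +S gave 8 after quantile normalization, 32 without the dimmest probe sets, 31 with trend and robust variances, 69 with array weights and 39 with the background filter, chosen after seeing the data. KO against Col at -S gave 997 without the dimmest probe sets, 180 with only the arrays compared (fewer arrays), 351 with array weights and 1045 with the background filter. OX against Col gave 279 without the dimmest probe sets, 260 with trend, 71 with only the arrays compared and 303 with the background filter, and the interaction gave 251 with trend and 284 with that filter. Col -S against +S gave 986 with only the arrays compared. With 1 probe set per gene, which tests fewer probe sets, the counts were 896, 616, 2, 262, 51 and 53 in the order named. Leaving out 1 array gave 897 to 2077, 564 to 1457, 4 to 59, 252 to 777, 36 to 131 and 84 to 205 in that order. The aliphatic list ranged from -3.21 to -2.74 in Col, 4.75 to 5.21 for KO at -S, -3.38 to -3.13 in OX and 4.45 to 4.91 for the interaction.

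With a replicate block for mutant line KO against Col at -S gave 487 and OX against Col 111, and no count moved by over 1.5 times. This block ended 4 of the 137 gene calls, those of PSAE1 and GR1 in Col, GH3.1 in KO against Col at -S and XTH19 in OX. With the Col number as a second block, though Col arrays share only a number (correlation -0.14), KO against Col at -S gave 342, OX against Col 75 and the interaction 106. Leaving out 1 array, the correlations of OX with KO at -S ran from -0.42 to -0.32, with Col at -S from 0.36 to 0.50 and with KO at +S from 0.17 to 0.48. With 1 Col +S array as control of each comparison, chosen after seeing the data, OX correlated with Col at -S at 0.3 or 0.25, and with KO at +S at 0.19 or -0.1. The cause was not tested. Signal over background limits the dim probe sets: 14679 of 22197 lay above background on both arrays of some group with the background levels rounded to 2 decimals, as in that filter, and 14664 with unrounded levels.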

Other observations

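The tests in this part were all chosen after the data were seen: 27 groups of at least 8 measured genes, families that share a symbol stem and the plastid-encoded genes, were tested with camera. Of 9 measured xyloglucan endotransglucosylases (XTH), which remodel cell walls, 4 rose in Col at low sulfate, XTH18 by 1.25 ± 0.17, XTH19 by 1.21 ± 0.21, XTH33 by 0.92 ± 0.15 and XTH26 at least 1.27-fold (limma adjusted p = 3e-04; camera adjusted p = 0.0023, and adjusted p = 0.78 with an estimated correlation), with 4 also after quantile normalization or median centring. In OX at +S 2 of 9 were called, XTH19 and, with both groups under the background level, XTH26 (camera adjusted p = 0.031, and adjusted p = 0.89 with an estimated correlation), but 1 after quantile normalization and 0 after median centring. Of 11 tau-class glutathione transferases (GSTU), 4 rose in KO at low sulfate, GSTU20, GSTU25 by 1.56 ± 0.20, GSTU27 by 1.38 ± 0.10 and GSTU22 by 1.01 ± 0.16 (camera adjusted p = 4.8e-05, and adjusted p = 0.57 with an estimated correlation), and 4 also rose by count under both scalings. GSTU25, GSTU27 and GSTU22 rose in Col at low sulfate too, where GSTU20 fell, and of the 11 the interaction was called for GSTU20 alone.

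Among 14 measured SWEET sugar transporters, SWEET14 and SWEET13 were lower in KO than in Col at -S (at least 2.19-fold, limma adjusted p = 0.00019, and -0.92 ± 0.10) and SWEET2 was higher (1.02 ± 0.14), while SWEET11 stood at -2.15 ± 0.49 (limma adjusted p = 0.057; camera adjusted p for the family = 0.019, and adjusted p = 0.27 with an estimated correlation), and 4 of the family were lower after quantile normalization. Of 69 measured plastid-encoded genes, 9 were higher in KO than in Col at -S, as were 9 after quantile normalization or median centring, and none lower, psbB by 0.92 ± 0.14 and rps2 by 0.78 ± 0.14 among them, and the median was 0.52, or 0.53 after quantile normalization (camera adjusted p = 2.8e-23, and adjusted p = 0.27 with an estimated correlation). In the same comparison the nuclear photosynthesis genes RCA, LHCB4.1 and PSAE1 stood at -0.16 ± 0.17, -0.22 ± 0.11 and -0.12 ± 0.18. The plastid-encoded genes were not shifted at -S alone. At +S their median was 0.15 in KO against Col, with 0 called (camera adjusted p = 8.9e-08, and 0.63 with an estimated correlation). It was also 0.15 in OX against Col, with 0 called (camera adjusted p = 0.086, and 0.89 with an estimated correlation). For the interaction the median was 0.33, with 1 called (camera adjusted p = 8.4e-08, and 0.45 with an estimated correlation).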
